A study of Mus musculus with 5 samples.

How the data were processed

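Total RNA was taken from undifferentiated mouse embryonic stem cells of strain C57BL/6, 2 wild-type and 3 Mkl2-/- cultures. Per the labels' protocols, the cells grew on gelatin and feeder fibroblasts with serum and leukaemia inhibitory factor, and feeders were removed before lysis by letting them attach to a dish for 1 h. RNA was purified on columns, amplified, turned into single-stranded cDNA and labelled with biotin for Affymetrix whole-transcript arrays. The removal step can leave some fibroblasts behind, so fibroblast markers were followed as a list of their own. The deposited values are log2 intensities made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, applies quantile normalization and summarizes the probes of a feature, which compresses differences of dim features. The deposited log2 values run from 3.39 to 14.26, are rounded to 2 decimals, and have array medians between 7.94 and 7.98. Further settings, scan dates and batches are not given in the sources used here. The series' design text calls the cultures independent, and nothing in the sources says whether they come from 1 or several cell lines per genotype. The p-values of single genes therefore measure the spread between cultures and not between lines.

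The table holds 35556 features on 5 arrays, and 0 columns of per-sample values were left unused. A platform annotation gave 1 gene symbol to 21789 features, several to 1621 and none to 12146. Of the features with 1 symbol, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, 91 did not, and 0 symbols changed. That table was used for names, chromosomes and the order of neighbouring genes, and no coordinates are given because the build behind the array annotation is not given in the sources used here. For each gene the feature with the highest mean over all 5 arrays was used, which gave 19938 genes; 999 genes had several features. The background level was the 95th percentile of the means of 1027 olfactory receptor genes, which was 7.30; 13564 genes lay above it. Where a named changed gene's lower group had arrays below it, those arrays were set to 7.30 and the fold is given as a bound; where both groups lay below it, no fold is given.

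Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (default prior, no trend), with 3 residual degrees of freedom, a prior of 0.885 degrees of freedom, and Benjamini-Hochberg adjustment over all 19938 genes. The threshold was an adjusted p of 0.05, and all tests count both directions. In 776 genes no array differed from its group mean at 2 decimals, 766 of them with the same value on all 5 arrays; limma offsets such zero variances, which lowers the prior degrees of freedom. Gene lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and again with the correlation estimated for each list. With the preset correlation, camera p-values of lists and chromosomes set genes against other genes and do not measure the spread between cultures. Of 738 listed symbols 672 were measured. The lists, the tests, the naming rule and all alternatives not described as added were fixed before the data were examined. By the naming rule, the text names Mkl2, Mkl1, Myocd and Srf, the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays do not overlap (leaving out predicted gene models and the Olfr, Vmn and Mup families), and up to 4 members of each list with the smallest p. Other list members and neighbouring genes named were chosen after their values were seen.

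Neighbouring genes were scanned with a running median of the differences over 25 expressed genes (13525 genes on the autosomes and X), after the data were seen. The threshold of 0.20 was the 95th percentile of the largest absolute running median in 1000 shuffled gene orders. The fit was tested on simulated data, with 19938 genes drawn from the measured means and spreads and 50 genes changed at each fold. It recovered 60% of genes changed 1.25-fold, 58% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and made 9 false calls among 165. The simulated noise was independent between genes and far fewer genes were changed than were called in the data. These rates therefore need not hold for the data. The scan recovered 97.5% of a block of 40 genes lowered by 0.3 and 27% of a block of 100 genes lowered by 0.2, and found 0 runs in shuffled differences. Alternatives were cyclic loess and quantile normalization, 2 filters on dim genes, eBayes with trend and robust, array weights, the mean of a gene's features, all features, no moderation, a 1.5-fold minimum, the replicate number as a block, the fibroblast marker mean as a covariate, each array left out, and for lists an estimated correlation, fry and removal of genes shared with the fibroblast list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.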

Results

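Gene expression was measured in undifferentiated mouse embryonic stem cells labelled wild type or Mkl2-/-. Mkl2, whose current symbol is Mrtfb, encodes a myocardin-related transcription factor, a partner protein of serum response factor (SRF). The series asks how loss of Mkl2 affects TGF-beta signalling in embryonic stem cells. There were 2 wild-type and 3 Mkl2-/- arrays, each from an independent culture of C57BL/6 cells. Values are log2 expression as deposited, and a difference is always Mkl2-/- minus wild type. Each array held 35556 features, of which 1 feature for each of 19938 named genes was tested. The number of arrays limits the precision of every value.

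By correlation and SD of the differences, replicate arrays of a group were closer to each other than to arrays of the other group. Across the 19938 genes, Pearson correlations lay between 0.998 and 0.999 within groups and between 0.992 and 0.994 between groups. The SD of the gene-wise differences was 0.080 to 0.111 within groups and 0.216 to 0.255 between groups. Other measures did not fully separate the groups: the median absolute difference was 0.05 between wild-type replicates 1 and 2 and also between wild-type replicate 1 and Mkl2-/- replicates 1 and 2. Wild-type replicate 1 shared 27.5% and 26.5% of its values to 2 decimals with those Mkl2-/- arrays, against 19.4% with wild-type replicate 2. The first principal component, with 80.7% of the variance, separated wild-type arrays (-16.8 and -20.2) from Mkl2-/- arrays (11.4, 11.7 and 13.9). No pair of arrays held identical values throughout, so all 5 were kept as separate replicates. On all 5 arrays, 766 genes had the same value to 2 decimals.

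The Mkl2 transcript was lower in all 3 Mkl2-/- arrays but stayed well above background. Mkl2 lies on chromosome 16 and has 3 features. Feature 10433633 read 9.80 and 9.75 in wild type and 9.32, 9.32 and 9.09 in Mkl2-/-. Its difference was -0.53 ± 0.09 (SE, n = 2 and 3; 1.45-fold lower, limma adjusted p = 0.048). The other features differed by -0.83 ± 0.07 (feature 10433639) and -0.98 ± 0.11 (feature 10433656). In the limma fit of all 35556 features, these 2 had adjusted p-values of 0.021 and 0.031, and feature 10433633 had 0.067. The background level, taken from 1027 olfactory receptor genes, was 7.30. Whether any of these features lies in the deleted part of the gene is not given in the sources used here, so the remaining signal is no check of the deletion. The adjusted p of feature 10433633 ranged from 0.038 to 0.189 when single arrays were left out, and it passed only without Mkl2-/- replicate 3. Among the relatives of Mkl2, Mkl1 (Mrtfa; 0.01 ± 0.015, adjusted p = 0.664) and Myocd (0.10 ± 0.06, adjusted p = 0.403, below background) did not pass the test. Srf itself differed by -0.16 ± 0.04 (adjusted p = 0.0997).

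**Figure D1:**
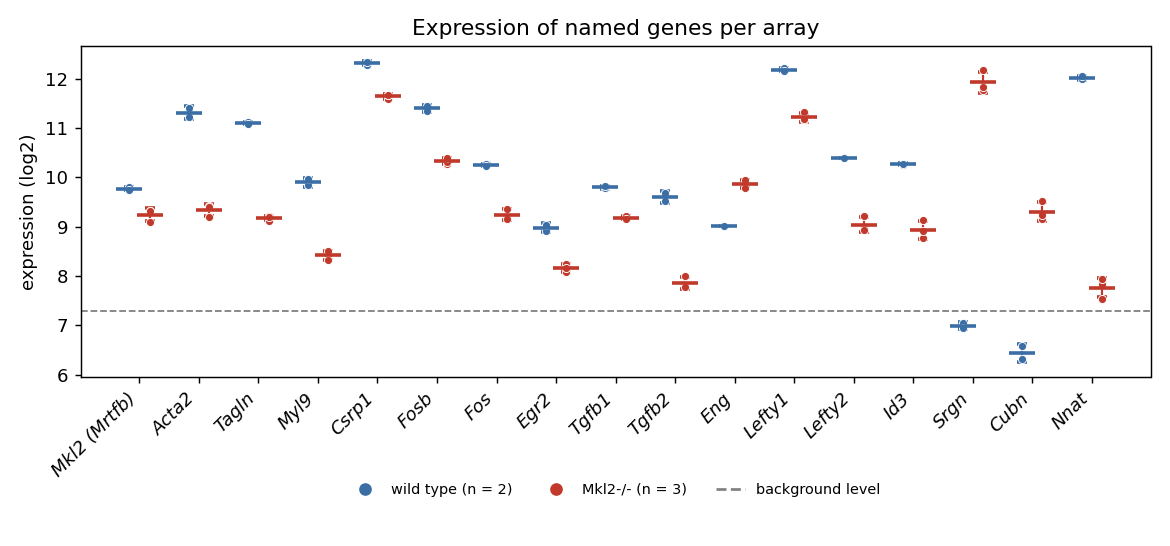
Expression (log2) of 17 named genes on each array. Points are single arrays, wide bars the group means and thin bars 1 SD, in blue for wild type (n = 2) and red for Mkl2-/- (n = 3); the dashed line is the background level of 7.30. Acta2, Tagln and Nnat lie lower in every Mkl2-/- array, and Srgn and Cubn cross from below the background level to 11.9 and 9.31.

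Some single genes differed strongly between Mkl2-/- and wild-type cells. Srgn, which encodes the proteoglycan serglycin, rose at least 24.7-fold, to 11.9 (limma adjusted p = 0.0054), and Cubn, which encodes the endocytic receptor cubilin, rose at least 4.02-fold, to 9.31 (adjusted p = 0.0079). Both lay below the background level on the 2 wild-type arrays (means 6.99 and 6.44), and a bound of this kind sets arrays below that level at 7.30. Nnat, an imprinted gene expressed from the paternal allele, fell 19.1-fold, to 7.77 (-4.25 ± 0.13). Uty, a Y-linked histone demethylase family gene, fell at least 3.86-fold, from 9.25 to below background on all 3 Mkl2-/- arrays (mean 5.61, adjusted p = 0.0041). The smooth muscle genes Acta2 (-1.97 ± 0.10) and Tagln (-1.93 ± 0.035) fell 3.92-fold and 3.81-fold.

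In total 1848 of the 19938 genes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 596 of them higher and 1252 lower in Mkl2-/-. Of these, 504 differed by at least 1.5-fold (96 higher, 408 lower) and 134 by at least 2-fold (19 higher, 115 lower). Without reference to a test, 552 genes differed by at least 1.5-fold with no overlap between the arrays of both groups. Chance gives no overlap to 20% of genes in this design, against 33.6% observed over all genes. Higher genes made up 32.3% of the calls, and 43.2% (1254 higher, 1652 lower) after quantile normalization on top of the deposited values. The number of calls fell with any array left out, and their split depended on which one. Each such fit also had fewer residual degrees of freedom, so the drop alone is no mark of a particular array. The count of genes with at least a 1.5-fold difference and no overlap stayed between 519 and 617. Without wild-type replicate 1 there were 963 calls in a nearly even split (473 higher, 490 lower; 49.1% higher), so the excess of falls was not kept there. There were 0 calls without wild-type replicate 2, where 4411 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.058. Without Mkl2-/- replicates 1, 2 and 3 there were 333, 403 and 448 calls, of which 24.0%, 23.3% and 27.2% were higher. All 1848 genes kept the sign of their difference in each of these fits, so every call on a single gene given here was lost without wild-type replicate 2 while its direction was not.

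By fitted difference, the other large rises were in Mir377, Mir382, Meg3 and DQ267102, which are neighbours on chromosome 12, and in Platr8, Slc23a1 (a vitamin C transporter), Cyp2b23, Rab25 (an epithelial small GTPase), Lama1 (a basement membrane laminin chain) and Zfp979. Their differences ran from 1.28 (Zfp979) to 1.82 (Mir377), but Mir382 and Platr8 lay below background on both wild-type arrays, so their rises were at least 2.06-fold and 2.45-fold. The other large falls were in the microRNA genes Mir302a, Mir302b and Mir302c of chromosome 3, Alox15 (a lipoxygenase), Gria3 (a glutamate receptor subunit), Serpinb9 (a protease inhibitor), and the X-linked genes Scml2 and Rps6ka3. Alox15 and Rps6ka3 stayed above background, with differences of -1.98 and -1.95. Below background on all 3 Mkl2-/- arrays lay Gria3 (at least 2.79-fold lower), Mir302c (at least 1.90-fold), Mir302a and Serpinb9 (each at least 1.59-fold) and Mir302b (at least 1.39-fold). Scml2 was below it on 2 of 3 Mkl2-/- arrays and at least 5.60-fold lower. Scml2 and Rps6ka3 belong to a stretch of 40 neighbouring X-linked genes with a median difference of -0.66, and the chromosome 12 genes to a stretch of 22 neighbours with a median of 0.66.

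Contractile and actin cytoskeletal genes known as targets of SRF and its myocardin-related partners fell more often than they rose. Of 44 measured members, 25 fell, none rose and 19 did not pass the test (0 rose and 31 fell when adjusted over the list alone). Besides Acta2 and Tagln, the regulatory light chain gene Myl9 (-1.49 ± 0.07) and the LIM protein gene Csrp1 (-0.68 ± 0.04, on chromosome 1) had the smallest p-values. Further falls included Cnn1 (-1.54), Palld (-1.41), Cald1 (-0.77) and Vcl (-0.45), while Actb differed by -0.01 and Myh11 by -0.01, neither past the test. The list's median difference was -0.28 (camera adjusted p = 1.1e-18, and adjusted p = 0.056 with an estimated correlation). Serum response genes of the other SRF arm, which works with ternary complex factors, also fell: 10 of 22 members fell and none rose (1 rose and 13 fell when adjusted over the list alone). Fosb (-1.07 ± 0.05), Fos (-1.01 ± 0.07), Egr2 (-0.81 ± 0.07) and Maff (-0.40 ± 0.04) had the smallest p-values of this list, and Egr1 (-0.72) and Nr4a1 (-0.54) also fell. Its median was -0.26 (camera adjusted p = 1.8e-07, and adjusted p = 0.24 with an estimated correlation). Of the 8 genes of the myocardin family and its SRF partners, Mkl2 fell, and Elk3 fell by 0.07 with no spread within either group (4 fell when adjusted over the list alone; camera adjusted p = 0.108, and adjusted p = 0.24 with an estimated correlation). Markers of fibroblasts, the feeder cells on which the stem cells grew, are given as a measure of carried-over cells: 5 of 42 fell and 3 rose (12 and 3 when adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.0021, and adjusted p = 0.21 with an estimated correlation). Igfbp4 (-0.99) and Has2 (-0.76) fell, Mmp2 (-0.26) fell, Crip1 (0.35) rose, and the collagen genes Col1a1 (-0.29), Col1a2 (-0.08) and Col3a1 (0.05, on chromosome 1) did not pass the test.

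**Figure D2:**
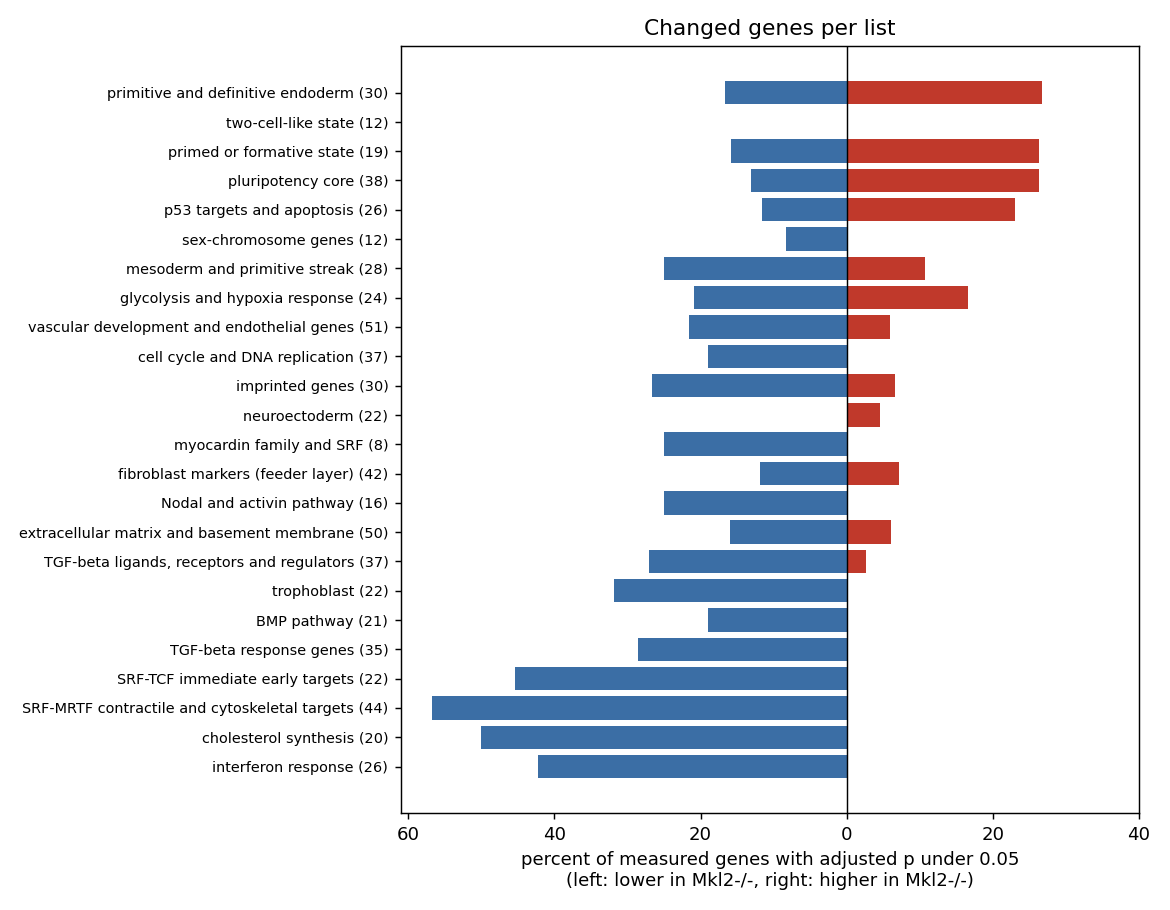
Percent of the measured genes of each of 24 lists that passed an adjusted p of 0.05, lower in Mkl2-/- to the left and higher to the right, with the number of measured genes in parentheses. Lists are ordered by median difference, from -0.40 for interferon response genes at the bottom to 0.07 for endoderm genes at the top.

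TGF-beta pathway genes fell more often than they rose. Tgfb2 fell 3.35-fold (-1.75 ± 0.09) and Tgfb1 1.53-fold (-0.61 ± 0.03), both ligands, and the co-receptor gene Nrp2 fell by 0.80 on the log2 scale. Eng, which encodes the accessory receptor endoglin, rose 1.81-fold (0.85 ± 0.06). Of 37 ligands, receptors and regulators, 10 fell, 1 rose and 26 did not pass (13 and 2 when adjusted over the list alone), with Smad3 (-0.46), Tgfbr3 (-0.45) and Itgb5 (-0.72) among those that fell and Tgfbr1 (-0.11) and Tgfbr2 (0.00) among those that did not pass. The median was -0.11 (camera adjusted p = 2.2e-05, and adjusted p = 0.091 with an estimated correlation). Tgfb2 and Nrp2 lie on chromosome 1, whose 758 expressed genes had a median difference of -0.17. Genes commonly induced by TGF-beta fell in 10 of 35 cases and rose in none (16 fell and 1 rose when adjusted over the list alone). They included Tagln, Snai1 (-0.53 ± 0.03), Ldlrad4 (-0.29 ± 0.01), Mmp2 (-0.26 ± 0.02), Timp3 (-0.84) and Fn1 (-0.61, on chromosome 1), while Smad7 (-0.18) and Skil (0.15) did not pass, and 6 of the 35 are also among the fibroblast markers. The median was -0.17 (camera adjusted p = 7.8e-08, and adjusted p = 0.088 with an estimated correlation). Of the response genes that fell, Tagln, Itga5 (-0.41) and Thbs1 (-0.46) also stand in the list of contractile SRF targets. Thbs1 is a member of the ligand and regulator list too, so the falls of these lists are not fully separate evidence.

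In the Nodal and activin branch, the ligand gene Nodal and some inhibitor genes fell. Lefty2 fell 2.54-fold (-1.35 ± 0.10), Lefty1 1.95-fold (-0.96 ± 0.06), Fst, which encodes the activin antagonist follistatin, 1.54-fold (-0.62 ± 0.05) and Nodal 1.38-fold (-0.46 ± 0.06). These were the 4 of 16 members that passed, over all genes as well as adjusted over the list alone; Lefty1 and Lefty2 lie on chromosome 1. The ligand genes Inhba (-0.255), Inhbb (-0.03) and Gdf3 (-0.02) did not pass. The median was -0.07 (camera adjusted p = 4.8e-04, and adjusted p = 0.091 with an estimated correlation). In the BMP branch 4 of 21 genes fell and none rose (9 fell when adjusted over the list alone): Id3 (-1.33 ± 0.12), Bmp7 (-0.94 ± 0.07), Bmp4 (-0.88 ± 0.09) and Dusp9 (-0.17 ± 0.03). Id1 differed by -0.45 without passing the test. Here the median was -0.14 (camera adjusted p = 4.3e-05, and adjusted p = 0.091 with an estimated correlation). In a fit without chromosome 1 and the shifted stretches of other chromosomes, an alternative added after the data were seen, the ligand and receptor list had 7 falls among 33 genes (camera adjusted p = 3.8e-05, and adjusted p = 0.13 with an estimated correlation) and the Nodal list 2 among 12 (camera adjusted p = 0.0040, and adjusted p = 0.18 with an estimated correlation).

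Extracellular matrix genes moved both ways. Efemp1, which encodes fibulin-3, fell 3.51-fold (-1.81 ± 0.10), Adamts1 (-0.91 ± 0.03) and Fbln1 (-0.42 ± 0.01) fell, and Lama1 rose 2.74-fold (1.45 ± 0.08). Of 50 genes 8 fell and 3 rose, and 12 of the 50 are also among the fibroblast markers (13 and 3 when adjusted over the list alone; median -0.09, camera adjusted p = 2.2e-04, and adjusted p = 0.21 with an estimated correlation). Of 51 vascular and endothelial genes, 11 fell and 3 rose (13 and 6 when adjusted over the list alone). Flt1, a VEGF receptor gene, fell 1.85-fold (-0.89 ± 0.015), the Notch target Hes1 1.88-fold (-0.91 ± 0.04) and the angiopoietin receptor gene Tek 1.15-fold (-0.20 ± 0.01). Vegfb (0.30 ± 0.02), Eng and Pdgfra (0.75) rose. This list's median was 0.01 and its mean -0.08, and the test of the whole list did not pass (camera adjusted p = 0.065, and adjusted p = 0.24 with an estimated correlation). It passed as lower after quantile normalization (camera adjusted p = 0.020), among genes with a mean above the median gene (camera adjusted p = 0.0073) and without chromosome 1 and the shifted stretches (camera adjusted p = 0.035, and adjusted p = 0.198 with an estimated correlation), so this call depended on the processing.

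Pluripotency genes changed in both directions, with no difference past the test in Pou5f1 (0.03) or Sox2 (0.07). Nanog fell 2.20-fold (-1.14 ± 0.07) and Klf4 1.61-fold (-0.69 ± 0.03; it lies among 30 neighbouring genes of chromosome 4 with a median of -0.35). Dnmt3l (0.94 ± 0.05) and Dppa2 (0.55 ± 0.03) rose. Over the list, 10 of 38 genes rose and 5 fell (14 and 10 when adjusted over the list alone; median 0.03, camera adjusted p = 0.48, and adjusted p = 0.84 with an estimated correlation). Of 19 genes of the primed or formative state, 5 rose and 3 fell (7 and 4 when adjusted over the list alone), with Lef1 (0.73 ± 0.07), Tcf15 (0.66 ± 0.06) and Otx2 (0.43 ± 0.04) higher and the kinase gene Pim2 (-0.87 ± 0.07) lower (median 0.04, camera adjusted p = 0.32, and adjusted p = 0.57 with an estimated correlation).

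Some markers of early mesoderm fell, and markers of endoderm changed in both directions. Sp5 (-1.28 ± 0.06), Wnt3 (-0.96 ± 0.06), Mixl1 (-0.75 ± 0.03, on chromosome 1) and Fgf8 (-1.12) fell, with 7 falls and 3 rises among 28 mesoderm and primitive streak genes (7 and 4 when adjusted over the list alone). That list's median was 0.02, its mean -0.11 and its test not passed (camera adjusted p = 0.22, and adjusted p = 0.71 with an estimated correlation). Of 30 endoderm genes 8 rose and 5 fell (9 and 6 when adjusted over the list alone), among them Srgn, Cubn, Lama1, Gata4 (0.93) and Gata6 (0.94) upwards and the keratin genes Krt19 (-0.69 ± 0.05), Krt8 and Krt18 downwards. Sox17 (0.33, on chromosome 1), Foxa2 (0.00) and Afp (0.06) did not pass (list median 0.07, camera adjusted p = 0.22, and adjusted p = 0.78 with an estimated correlation). Of 22 neuroectoderm genes, Neurod1 rose (1.23 ± 0.09) and none fell, also when adjusted over the list alone; Stmn2 (-0.21), Fabp7 (-0.65) and Sox11 (-0.18) did not pass (median -0.02, camera adjusted p = 0.115, and adjusted p = 0.24 with an estimated correlation). The neuroectoderm list passed as lower without wild-type replicate 2 (camera adjusted p = 0.0308, range to 0.314 over the arrays left out). Trophoblast genes fell in 7 of 22 cases (7 fell and 1 rose when adjusted over the list alone), including Krt8 (-0.54 ± 0.05), Cdx2 (-0.37 ± 0.03), Mmp9 (-0.30 ± 0.03) and Tfap2a (-0.27 ± 0.02), with a median of -0.11 (camera adjusted p = 1.9e-04, and adjusted p = 0.091 with an estimated correlation). None of 12 genes of the 2-cell-like state passed, over all genes or over the list alone, with Eif1a (0.06) nearest to it, ahead of Zfp352 (0.11), Arg2 (0.17) and Pramel7 (0.05); 1 of the 12 lay above background (median 0.05, camera adjusted p = 0.22, and adjusted p = 0.44 with an estimated correlation).

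Imprinted genes included some of the strongest changes. Besides Nnat, the paternally expressed genes Plagl1 (-1.10 ± 0.07), Igf2 (-1.02 ± 0.03), Mest (-0.55 ± 0.03), Peg3 (-0.58) and Sgce (-0.35) fell. Of maternally expressed genes, Phlda2 (-0.59) fell, and the RNA genes Meg3 (1.37 ± 0.09) and Rian (1.09) rose, both in the same stretch of chromosome 12. Zim1 passed the test as lower but lay below background in both groups (7.06 and 6.82), so no fold is given. Over the list 8 of 30 fell and 2 rose (9 and 4 when adjusted over the list alone; median -0.02, camera adjusted p = 0.019, and adjusted p = 0.19 with an estimated correlation). This list's adjusted p was 0.0501 without wild-type replicate 2, the highest of a range from 0.0169 when single arrays were left out. Of 12 sex-chromosome genes only Uty changed, also when adjusted over the list alone. The Y-linked gene Eif2s3y was at 10.8 in wild type and 10.6 in Mkl2-/- (-0.20 ± 0.10, adjusted p = 0.370), Kdm5c differed by 0.06, and Xist lay below background (0.21). The list's median was 0.03 and its mean -0.30 (camera adjusted p = 0.76, and adjusted p = 0.88 with an estimated correlation).

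Cholesterol synthesis and interferon response genes fell more often than they rose, though neither list passed with an estimated correlation. Of 20 cholesterol genes 10 fell, none rose and 10 did not pass (14 fell when adjusted over the list alone), with Hsd17b7 (-0.67 ± 0.05, on chromosome 1), Sc5d (-0.37 ± 0.01), Stard4 (-0.36 ± 0.03) and Fdft1 (-0.24 ± 0.01) having the smallest p-values. The median was -0.31 (camera adjusted p = 6.2e-12, and adjusted p = 0.091 with an estimated correlation). Of 26 interferon response genes 11 fell, none rose and 15 did not pass (15 fell when adjusted over the list alone), with the smallest p-values in Gbp3 (-1.18 ± 0.06), the proteasome subunit gene Psmb8 (-1.05 ± 0.09), the transcription factor gene Irf1 (-0.83 ± 0.03) and Ifit1, which lay close to the background level (7.35 in wild type and 6.88 in Mkl2-/-, at least 1.04-fold lower). Usp18 (at least 1.93-fold lower), Oasl2 (-0.79) and Cxcl10 (-0.79) also fell. Their median was -0.40 (camera adjusted p = 3.2e-09, and adjusted p = 0.091 with an estimated correlation). The remaining lists did not pass the test as wholes. Of 26 p53 and apoptosis genes 6 rose and 3 fell (9 and 5 when adjusted over the list alone), with Mdm2 (0.52), Plk2 (0.50) and Ei24 (0.29) higher and Gadd45b (-0.94) lower (camera adjusted p = 0.58, and adjusted p = 0.80 with an estimated correlation). Of 37 cell cycle genes 7 fell and none rose, also when adjusted over the list alone, including Ccnd2 (-0.93), Ccnd1 (-0.32), Cdc6 (-0.32) and Mcm6 (-0.41, on chromosome 1), while Mki67 differed by -0.02 without passing (camera adjusted p = 0.21, and adjusted p = 0.57 with an estimated correlation). The cell cycle list passed as lower without wild-type replicate 1 (camera adjusted p = 0.0358, range to 0.586 over the arrays left out). Of 24 glycolysis and hypoxia genes 4 rose and 5 fell, also when adjusted over the list alone, with Pfkl (0.36) and Ldha (0.14) higher and Hk2 (-0.79, among 150 shifted neighbours on chromosome 6) and Slc2a3 (-0.68) lower (camera adjusted p = 0.93, and adjusted p = 0.95 with an estimated correlation). This list's median was 0.02 and its mean -0.04. Altogether 12 of the 24 lists passed camera with the preset correlation of 0.01, all of them lower in Mkl2-/-, and 0 of 24 passed with an estimated correlation. Some estimates exceeded the preset one, such as 0.354 for the serum response genes. Others lay below it: 0.0065 for contractile, 0.0005 for TGF-beta response, -0.005 for Nodal and -0.015 for trophoblast genes. For lists of the latter kind, the lost call does not reflect a stronger correlation among members.

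**Figure D3:**
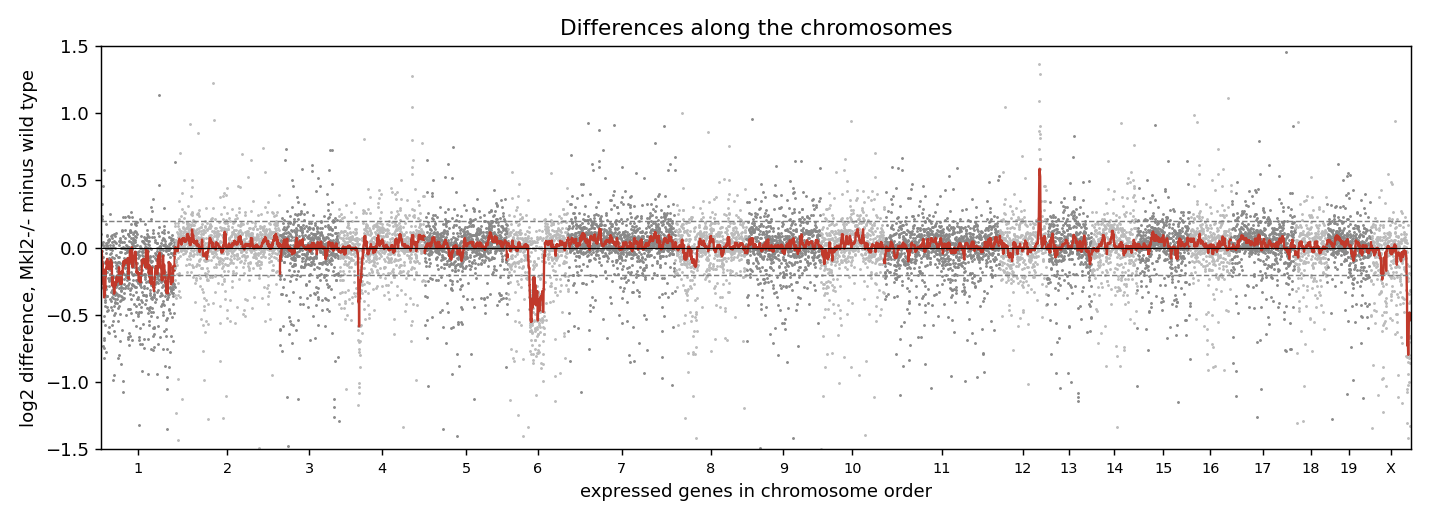
Difference of each of 13525 expressed genes (points) in chromosome order, with the running median over 25 neighbouring genes (red) and the threshold of ±0.20 that 95% of shuffled gene orders stayed within (dashed); 29 genes lie outside the axis range. Genes of chromosome 1 had a median of -0.17, with lower stretches on chromosomes 4, 6 and X (medians -0.35, -0.40 and -0.66) and a raised one on chromosome 12 (median 0.66).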

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

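The fits without chromosome 1 and the shifted runs, without genes equal on all 5 arrays, and with another Mkl2 feature were chosen after the data were seen. Over all alternatives, 1214 values of named genes kept their side of the threshold, 480 lost the call, 17 gained one and 0 reversed. For gene lists these numbers were 422, 19, 12 and 1. A change of sign counted as reversed only where the main or the alternative fit passed the threshold, and otherwise as kept. Xist, for example, was kept throughout with differences from -0.326 to 0.265. Where no reason is given, the cause was not tested.

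The 1848 calls (596 higher, 1252 lower) became 2949 (970, 1979) after cyclic loess and 2906 after quantile normalization (1254 higher). Without moderation there were 294 (64 higher, 230 lower), and with a 1.5-fold minimum, which by construction only removes calls, 504 (96 higher, 408 lower). Without chromosome 1 and the runs 791 genes were lower, with fewer genes tested, and Mkl2 kept its difference of -0.53 at an adjusted p of 0.0565. With the Mkl2 feature brightest in wild type, the difference was -0.98 (limma adjusted p = 0.021). Without the 766 equal genes 899 were higher. Leaving out single arrays gave 0 to 963 calls, 963 without wild-type replicate 1 (473 higher, 490 lower, so the excess of falls was lost), and Mkl2 differences of -0.57 to -0.455; with 1 wild-type array left, that array is assumed to vary like the Mkl2-/- arrays. The count of genes with at least a 1.5-fold difference and no overlap, 552, was 1055 with the fibroblast covariate and 1339 over all features. Of these features, 597 had 1 gene symbol, 89 had several and 653 had none. The count of such genes stayed between 519 and 617 when single arrays were left out.

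With the replicate number as a replicate block, limma called 0 genes (0 higher, 0 lower; 3827 at an unadjusted p under 0.05, smallest adjusted p 0.161), and Mkl2 differed by -0.455 (adjusted p 0.161, against a range of 0.038 to 0.189 over arrays left out). The block leaves Mkl2-/- replicate 3 out of the contrast. The deviations of same-numbered arrays from their group means correlated at -0.201 (number 1) and 0.191 (number 2). Those of wild-type replicate 1 and Mkl2-/- replicate 3, which share no number, correlated at 0.313. With 2 wild-type arrays the deviations of both are mirror images, so this check cannot decide whether same-numbered arrays belong together. With the mean of the fibroblast markers as a covariate, limma called 0 genes (0 higher, 0 lower), with 1195 at an unadjusted p under 0.05. Mkl2 differed by -0.55 (adjusted p 1), close to -0.53 in the main fit, but its SE rose from 0.089 to 0.512. This fit separates covariate and genotype poorly, so the lost calls do not show that feeders account for them. In it 7 lists shifted, and the fibroblast list had a median of 0.023 in place of -0.06, which the covariate brings about by construction. With an estimated correlation 0 of 24 lists shifted, against 12 with the preset one, though the estimates of some lists lay below the preset 0.01. The method fry, which does not compare a list with other genes, called 19. The vascular list was not called in the main fit (camera adjusted p 0.065). It was called as lower after quantile normalization (0.020), among genes with a mean above the median gene (0.0073) and by fry (0.0027). It was also called without chromosome 1 and the runs (0.035, but 0.198 there with an estimated correlation). The imprinted list lost its call among genes above background (0.118), with the replicate block and with the fibroblast covariate. The matrix, trophoblast and interferon lists also lost theirs with that covariate. Signal limits the rest: 13564 of 19938 genes lay above the background level, and differences of dimmer genes are compressed.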

Other observations

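The tests of the copy-number, fibroblast and regional explanations, and the scan itself, were chosen only after the results were seen; the brightness and single-feature tests of chromosome 1 were set before their values were seen. Differences between Mkl2-/- and wild type were grouped by chromosomal position. Of 758 expressed genes of chromosome 1, 230 fell and 7 rose, with a median of -0.17 and 76.6% of genes below 0, against a median of 0.015 and 42.6% for the 12520 expressed genes outside chromosome 1 and the runs (camera adjusted p = 1.7e-16 over 20 chromosomes, and adjusted p = 0.058 with an estimated correlation). Its 364 genes below background had a median of 0.02, and its estimated correlation was 0.009, below the preset 0.01. Chromosomes X, 6 and 7 also passed with the preset correlation (camera adjusted p = 1.9e-04, 0.028 and 0.015). With an estimated correlation they did not (camera adjusted p = 0.49, 0.25 and 0.40). Chromosome 7 had a median of 0.04, with 67 rises and 54 falls. A run of 150 neighbouring genes on chromosome 6, from Krcc1 to Adamts9, had a median of -0.40 with 79 falls and 0 rises, among them the hexokinase gene Hk2 (-0.79), the helicase gene Mcm2 (-0.47) and the Wnt pathway repressor gene Tcf7l1 (-0.72). On chromosome 4, 30 genes from Rad23b to Prpf4 had a median of -0.35 with 16 falls and 0 rises, including Lpar1 (-1.08), Ugcg (-0.70) and Klf4 (-0.69). On X, 40 genes from Acot9 to Mid1 had a median of -0.66 with 28 falls and 0 rises, including Scml2 (at least 5.60-fold lower), Rps6ka3 (-1.95), Map3k15 (-1.70) and the pyruvate dehydrogenase gene Pdha1 (-1.41). In each of these runs the medians of all 3 Mkl2-/- arrays lay below those of both wild-type arrays.

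A run of the opposite sign lay within the imprinted Dlk1-Dio3 domain of chromosome 12, without Dlk1 and Dio3 themselves. From Meg3 to Mir377, 22 genes had a median of 0.66 with 12 rises and 0 falls, including Rian (1.09) and the microRNA genes Mir134 (0.85), Mir679 (0.82) and Mir341 (0.74). The domain's protein-coding genes Dlk1 (0.11), Rtl1 (0.22) and Dio3 (0.04) did not pass the test. The 20 nearest measured neighbours of Mkl2 on chromosome 16 had a median of 0.03, and 3 of them passed. All 3 were higher and lay on the same side of Mkl2: Pla2g10 (0.935), Mpv17l (0.35) and Rrn3 (0.24). The cause was not tested. Among the 12146 features with no gene symbol, 653 differed by at least 1.5-fold with no overlap between groups (156 higher, 497 lower) and 343 passed the test over all features. Of the 21789 features with 1 symbol, 597 differed in this way and 1441 passed. Above background lay 6524 of the features with no symbol and 14840 of those with 1 symbol.

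The lower values of chromosome 1 were weighed against technical explanations. A trend with brightness left by the normalization was argued against: cyclic loess left the median of the 758 genes at -0.18 (95% bootstrap interval -0.20 to -0.15), below the bound of -0.10 set in advance. The bootstrap intervals resampled genes or features as if independent, and not arrays, so they hold no spread between cultures. Sequence differences under single features were argued against too, but only for 43 of these genes. Their 99 other features had a median of -0.17 (interval -0.26 to -0.13), against -0.205 for the features used in the fit. Features of the same gene were resampled as if independent, so the interval may be too narrow. The remaining genes could not be tested this way. A copy-number difference between the wild-type and Mkl2-/- cells may underlie the shift: 76.6% of genes lay below 0, in step on all 3 Mkl2-/- arrays, but genotype and cell line cannot be told apart here, since the sources do not say how many lines each genotype comes from, no DNA was measured, and an effect of Mkl2 loss on these genes stays open and untested. Karyotypes or DNA copy number of the cells of each genotype, or further independent knockout clones, would test it. Of the TGF-beta family genes on this chromosome, Tgfb2 (-1.75 ± 0.09), Lefty2 (-1.35 ± 0.10) and Lefty1 (-0.96 ± 0.06) fell far beyond its median and its lower quartile of -0.33, so a shift of the whole chromosome of this size accounts for only a small part of their falls. A change at these genes alone was not tested.

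The fall of contractile SRF target genes was weighed against fewer feeder fibroblasts in the Mkl2-/- samples, given that feeders were removed by attachment. This stays open: the 33 fibroblast markers above background had a median of -0.083 (95% bootstrap interval -0.27 to -0.005), which includes -0.15, 0.5 times the median of the 41 contractile genes above background (-0.29), so a part from feeders cannot be told apart from the genotype. With the mean of the fibroblast markers as a covariate, the contractile list stayed lower and past camera with the preset correlation. Its median was -0.27 or lower in every alternative. The SE of the Mkl2 difference rose to 0.512 in the covariate fit, so that fit does not settle the question. The markers went both ways, with 5 lower, 3 higher and 25 not past the test; those brightest in wild type were Vim (mean 12.7 in Mkl2-/-, difference -0.32), Lgals1 (12.2, 0.00), Crip1 (10.9, 0.35), Mmp2 (9.74, -0.26) and Bgn (9.70, -0.17), Timp3 (-0.84), Igfbp4 (-0.99) and Has2 (-0.76) fell, and 16 of the 42 markers stand in other lists too. The regional shift was argued against as the cause, since the 36 contractile genes outside chromosome 1 and the runs had a median of -0.28 (interval -0.45 to -0.18), and all 38 measured ones there had a camera adjusted p of 0.038 with an estimated correlation. Both intervals of this paragraph resampled genes and not arrays, so they hold no spread between cultures. A direct effect of Mkl2 loss on SRF targets stays an untested hypothesis, which re-expression of Mkl2 in these cells, or its binding at these genes, would test.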
